A study of Triticum dicoccon x Aegilops tauschii subsp. strangulata and Aegilops tauschii subsp. strangulata and Triticum turgidum subsp. dicoccum with 15 samples.

How the data were processed

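Leaves of seedlings with 2 leaves were sampled from 5 lines, grown at 22 °C with 16 h of light and 8 h of dark per day, per the labels' protocols. Triploid embryos were rescued 2 weeks after pollination, and the doubled hexaploid came from selfing triploid plants treated with 0.2 percent colchicine, per the labels' protocols. From each sample 500 ng of RNA was labelled with Cy3, per the labels' protocols. The series describes 3 biological replicates per line. Arrays were read with Agilent Feature Extraction 9.5 per the submitters' processing notes, and with 9.5.1.1 per the file headers.

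The deposited scanner files give intensity on a linear scale: the processed signal is background-subtracted Cy3 brightness with a low surrogate for dim spots, per the file headers, and the mean signal and local background intensity are raw. Flags for spots well above background, saturated, non-uniform or outlying are also deposited, per the file headers. The deposited value table holds log2 values of 20802 probes by the authors. Set against the scanner values, its differences between arrays equal those of log2 processed signal apart from 1 constant per array (largest SD around it 5.1e-07). That constant matched the array's 75th percentile within 0.0037, and each probe had been centred. The column medians of the table ran from -0.0794 for stable replicate 2 to 0.146 for paternal replicate 1. Its direction follows the log2 signal, while its probe filter and exact centring stay unknown.

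Here, log2 of the processed signal minus the 75th percentile of each array was used. Of 37826 probes, 189 with a non-uniform or outlying spot on any array were left out, and 37637 stayed. The 28279 tested probes were well above background on all 3 arrays of at least 1 group. Saturated spots were kept. Group means were fitted to all 15 arrays at once with limma 3.58.1 (R 4.3.3, data.table version 1.17.8), without a block, and tested with eBayes and Benjamini-Hochberg adjustment at 0.05. A 3 against 3 comparison of positions used the exact permutation test. The mid-parent was log2 of the linear mean with weights 2 for the maternal and 1 for the paternal parent, and its error came from the delta method. Scripts in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots. No 2 arrays held identical values.

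The steps were tested on simulated data. For the triploid versus mid-parent comparison on 28279 probes, 32 of 100 probes changed by 1 on the log2 scale and 72 of 100 changed by 2 were recovered, with 8 false calls. Simulated unchanged lines gave 0 calls. The simulated arrays were not rescaled and had no slide effect, so these counts do not bound false calls in the real data.

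Probes to be named were fixed before the data were examined: for maternal versus paternal parent, each line versus mid-parent and each pair of lines, genes named by the annotation, or otherwise at most 2 probe names up and 2 down. Named probes passed the threshold and did not overlap between groups. The further condition that they be well above background on all arrays compared was added once no annotation was found, so that ranks rest on measured values. All 37826 probe descriptions read as unknown, and none had a genome position. Of the 32 keyword gene lists fixed beforehand, the list on cold, dehydration and late embryogenesis proteins matched 1 probe, that on transcription factors matched 2, and the others matched 0. None reached the minimum of 5 probes, so none was tested. No genome coordinates were used here.

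Array position and slide came from the file headers. Slides 1, 2 and 3 each held 1 array of the parents, the triploid and the stable hexaploid, with replicate number equal to slide number, and slide 4 held all 3 arrays of the doubled hexaploid. Same-numbered arrays sharing a slide deviated together from their group means, with r from 0.05 to 0.41 across probes in 18 pairs, 16 of them over 0.1. In the 12 pairs with the doubled hexaploid r ran from -0.12 to 0.08. Slide was therefore fitted as a fixed block on 12 arrays and as a random block on all 15 (correlation within slides 0.133).

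Alternatives planned before the data were examined were quantile normalization, median centring, normexp on mean and background intensity with offset 50, the deposited value table, other filters on dim probes, replicate and slide blocks, smaller fits, array weights, an intensity trend, a 2-fold minimum, other mid-parents, other probe sets for the position, and leaving out each array. Added after seeing the data were slide as a random block, a mid-parent rescaled to its own 75th percentile, removal of the trend with GC content and brightness, 1 probe per sequence cluster, the linear paternal share and paternal-only probes chosen without 1 maternal array.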

Results

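Messenger RNA levels were measured in leaves of seedlings at the 2-leaf stage from 5 lines, both parents of a cross and 3 synthetic wheats, with 3 biological replicates and 15 arrays in all. The maternal parent was the tetraploid Triticum turgidum ssp. dicoccum, emmer wheat, with genomes AABB. The paternal parent was the diploid goat grass Aegilops tauschii, with genome DD. The 3 synthetic lines recreate the cross that gave rise to bread wheat. They were a newly made triploid hybrid (ABD), the hexaploid obtained after its chromosomes were doubled (AABBDD), and a stable synthetic hexaploid (AABBDD). The labels give neither the generation of the stable hexaploid nor whether it came from the same parental stocks, so its values against the parents measured here hold for these parents only. Each sample was hybridised to its own 1-colour array of 37826 probes of 60 bases, designed from wheat expressed sequences. The summed processed signal ran from 51586783 in triploid replicate 2 to 115799801 in maternal replicate 1. Between 63.7 and 75.3 percent of the probes were well above background on an array. The number of arrays, 3 per group, limits the precision. Samples of the triploid group are called samples labelled triploid, since their profile closely resembled that of the maternal parent. Changes called widest are among probes well above background on every array compared. All levels are log2 of the signal minus the 75th percentile of the array, and changes are given with their standard error (SE). The files pair nearly all probes with clone or contig names only, so probes are named by these and not by genes.

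Whole-array profiles were compared first. Across the 28279 tested probes, which are not independent replicates, the correlation between a maternal and a paternal array was 0.549 to 0.579. A maternal array and an array labelled triploid correlated at 0.981 to 0.99, which overlaps the 0.986 to 0.989 among the maternal replicates themselves. Both hexaploids stood between the parents. The doubled hexaploid correlated with the maternal parent at 0.861 to 0.874 and with the paternal parent at 0.724 to 0.739. The corresponding ranges for the stable hexaploid were 0.853 to 0.895 and 0.708 to 0.76. A doubled and a stable hexaploid array correlated at 0.897 to 0.943, below the 0.972 to 0.99 among replicates of the doubled and the 0.963 to 0.975 among those of the stable hexaploid.

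The parents differed at 17928 of 28279 probes (63.4 percent; limma, Benjamini-Hochberg adjusted p under 0.05), of which 9089 were higher in the maternal and 8839 in the paternal parent. At 14373 of these the difference was at least 2-fold. Among probes measured in both parents, the widest maternal excess was at wheat0130Contig15729, by 11.11 on the log2 scale (SE 0.41, adjusted p = 1.154e-11), with a level of 6.71 ± 0.22 (SD, n = 3) in the maternal and -4.4 ± 0.41 in the paternal parent. Its probe is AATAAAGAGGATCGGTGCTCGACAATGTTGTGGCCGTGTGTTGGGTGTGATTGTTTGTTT. MUG005A07R990206 followed with 10.82 (SE 0.2). In the other direction rwhsh16b11_2 had a log2 change of -12.18 (SE 0.4, adjusted p = 3.239e-12), from 6.99 ± 0.44 in the paternal to -5.19 ± 0.53 in the maternal parent. Its probe is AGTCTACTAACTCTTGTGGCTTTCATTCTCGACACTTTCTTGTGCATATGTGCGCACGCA. The log2 change of rwhsh15n12 was -11.31 (SE 0.44). With normexp background correction, which damps dim probes, 9421 probes passed. The sizes depended on it too, and became 8.93 at wheat0130Contig15729, 7.7 at MUG005A07R990206, -9.98 at rwhsh16b11_2 and -9.99 at rwhsh15n12, all still called. The near-even balance turned in 6 of 15 other settings, with 45.3 percent higher in the maternal parent under quantile normalization, 42.6 under normexp, 42.1 under median centring and 41.5, the lowest, at probes well above background on all 15 arrays. Slides 1, 2 and 3 each held 1 array of both parents, and 15016, 15277 and 14924 probes differed at least 2-fold within them; with slide as a block on 12 arrays, leaving out the doubled hexaploid, the count stayed within 1.5 times.

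Samples labelled triploid were compared with each parent to address what the cross changed before chromosome doubling. They differed from the maternal parent at 6 probes, 4 higher and 2 lower, while 1142 had an unadjusted p under 0.05. They differed from the paternal parent at 17925 probes, with 9251 higher and 8674 lower (9297 in all with normexp), a balance that turned in 5 of 15 other settings, down to 41.9 percent higher. At wheat0130Contig7209, the level was -1.06 in these samples and -5.17 in the maternal parent, a change of 4.11 (SE 0.53, adjusted p = 0.02599, limma). At wheat0130Contig1954 the change was 3.03 (SE 0.41, adjusted p = 0.02734, limma). With normexp these changes were 2.37 (SE 0.49) at wheat0130Contig7209 and 2.11 (SE 0.7) at wheat0130Contig1954, and neither passed. MUGEST2003_23lib_Contig6252_p_1052 rose by 1.95. The other 3 calls rest on probes not well above background on every array of both groups, so no size is given. Of these, wheat0130Contig4242, the last of the higher probes, was so on 0 of 3 maternal arrays and 1 of 3 arrays labelled triploid. The lower probes wheat0130Contig6054 and wheat0130Contig4998 were so on 3 of 3 maternal arrays and 0 of 3 arrays labelled triploid. Dim in the maternal parent too was wheat0130Contig7209 (SD 1.19), though well above background on 3 of 3 arrays. All 6 were named after their values were seen, and wheat0130Contig7209 lost the call in 8 and wheat0130Contig1954 in 13 other settings. The count was 1 with slide as a fixed block on 12 arrays, leaving out the doubled hexaploid, and 14 with slide as a random block on all 15. It was 0 with normexp or with only these groups in the fit, 1 from the deposited table or with probes well above background on all 15 arrays, 3 without the filter on dim probes and 139 with array quality weights. It was 1 without maternal replicate 3, 2 without maternal or paternal replicate 1, 3 without paternal replicate 2 or doubled hexaploid replicate 3, 10 without stable hexaploid replicate 2 and 11 without triploid replicate 1. Within slides 1, 2 and 3, the samples labelled triploid and the maternal parent differed at least 2-fold at 1330, 1628 and 1398 probes, and they differed so from the paternal parent at 14978, 15627 and 14743. Pairs of maternal replicates differed so at 1397 to 2236 probes. Those pairs lay on different slides, so their range is not like for like with the counts within slides.

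Probes seen in 1 parent alone were then followed in the lines. There were 1388 paternal-only probes, well above background on all 3 paternal arrays and on no maternal array. Of these, 2 (0.1 percent) were well above background on all 3 arrays labelled triploid, against 789 (56.8 percent) in the doubled and 901 (64.9 percent) in the stable hexaploid. The 2 were MUGEST2003_23lib_Contig549_248 and whdl2f08, named after their values were seen. Among the 595 paternal-only probes at least 16 times over the floor, which is the lowest signal of a probe well above background on each array, the counts were 0, 580 and 584. Of these 595, 543 were on no array labelled triploid. Of 3277 maternal-only probes, 3098 were seen on all 3 arrays labelled triploid, 2630 in the doubled and 2868 in the stable hexaploid. Their median level, as a percentage of the maternal mean, was 98.7 ± 1.84 (SD, n = 3) in the samples labelled triploid. It was 57.2 ± 1.17 in the doubled and 60.5 ± 2.51 in the stable hexaploid. For paternal-only probes the percentage of the paternal mean was 23.6 ± 0.573 in the doubled and 25.3 ± 0.477 in the stable hexaploid. No level is given for the samples labelled triploid, where 86.2 percent of these probes were on no array.

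Both hexaploids differed from either parent. In the doubled hexaploid 6045 probes were higher and 7278 lower than in the maternal parent, 13323 in all, and 17917 differed from the paternal parent (7203 with normexp). The stable hexaploid differed from the maternal parent at 7831 probes, 4037 higher and 3794 lower, and from the paternal parent at 17020 (6111 with normexp). Without maternal replicate 1 the stable count against the maternal parent was 5120, and its near-even balance turned in 6 of 15 other settings, among them quantile normalization (41.2 percent higher) and median centring (47.4), and without paternal replicate 3 (49.7 percent higher), doubled replicate 1 (49.1) or stable replicate 3 (47.7). With normexp the counts against the maternal parent were 3380 for the doubled and 2193 for the stable hexaploid, and 64.1 and 89.4 percent of them were higher, in place of 45.4 and 51.6 percent. With a 2-fold minimum 51.2 percent were higher in the doubled hexaploid. Within slides 1, 2 and 3 the stable hexaploid and the maternal parent differed at least 2-fold at 6402, 9369 and 6139 probes, and the stable hexaploid and the paternal parent at 13102, 16389 and 12366. All 3 arrays of the doubled hexaploid shared slide 4, which held no other group, so that slide and group cannot be told apart for this line.

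The mid-parent, 2 parts maternal to 1 part paternal on the linear scale, gives the level of an even mix of the 3 genomes before array scaling. It was not rescaled, and its 75th percentile lies 0.201 above that of the arrays on the log2 scale. An additive line, scaled as the arrays are, would therefore read lower than it by that much. Samples labelled triploid departed from the mid-parent at 5853 probes, of which 1065 were higher and 4788 lower. With a 2-fold minimum 215 were higher and 3458 lower. A level equal to the maternal one can exceed such a mix by less than 2-fold but can fall far below it. The split therefore follows largely from the maternal-like profile of these samples. The fall was widest at paternal-higher probes, as at rwhsh15n12 (-10.51, SE 0.44, adjusted p = 4.24e-10) and whsh_allContig1255 (-9.87, SE 0.39), the latter at 8.01 in the paternal parent and -3.44 in these samples. The widest rises were at wheat0130Contig7209 (3.32, SE 0.46) and rwhoh20f22 (2.92, SE 0.6), the latter not past the threshold with normexp. The count was 2131 with normexp and 11964 with array quality weights, and 39.7 percent of calls were lower against a 2 to 1 mean of log2 values, in place of 81.8 percent. Within slides 1, 2 and 3, 4667, 5328 and 4708 probes lay at least 2-fold from the mid-parent of that slide.

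The doubled hexaploid departed from the mid-parent at 10434 probes, 2616 higher and 7818 lower. MUG020A12R990620 rose by 4.99 (SE 0.41, adjusted p = 1.301e-05, limma), to 0.25 from -4.75 in the maternal and -4.7 in the paternal parent. Its probe is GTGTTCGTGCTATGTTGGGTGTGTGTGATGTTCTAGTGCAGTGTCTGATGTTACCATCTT. The rise of whok9o07_136 was 3.63 (SE 0.27). The change of whsh_allContig984 was -5.08 (SE 0.3) and that of wheat0130Contig2525 was -4.8 (SE 0.28), both at probes higher in the paternal parent. The count was 1342 with normexp and 17501 with array quality weights, and 41.9 percent of calls were lower against a 2 to 1 mean of log2 values, in place of 74.9 percent.

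The stable hexaploid departed from the mid-parent at 1792 probes, 254 higher and 1538 lower. The 2 widest rises were at whsh_allContig688 (4.05, SE 0.57) and wheat0130Contig1335 (3.68, SE 0.78). Falls were widest at wheat0130Contig2525 (-3.78, SE 0.28, adjusted p = 2.193e-05, limma), which had fallen in the doubled hexaploid too, and wheat0130Contig11839 (-3.15, SE 0.79). The calls at whsh_allContig688, wheat0130Contig1335 and wheat0130Contig11839 were lost with normexp, and in all settings that at wheat0130Contig1335 was lost in 4 and that at wheat0130Contig11839 in 13. Among the settings that moved it by over 1.5 times, the count was 7165 with quantile normalization, 6610 with median centring, 4047 with slide as a fixed block on 12 arrays, 3238 with slide as a random block, 2889 with the replicate block, 4 with normexp, 607 against a mid-parent rescaled to its own 75th percentile, 499 without stable replicate 2 and 3413 without stable replicate 3, and it moved by over 1.5 times without any of 10 of the 15 arrays. Within slides 1, 2 and 3, 2763, 7003 and 2720 probes lay at least 2-fold from the mid-parent, the middle value being that of stable replicate 2. Against a 2 to 1 mean of log2 values, 28 percent of the calls were lower, in place of 85.8 percent.

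Tested probes were then sorted by which of the tests against each parent they passed. Where the parents differed, a probe like the maternal parent passed against the paternal parent alone, and an unresolved one passed against neither. Probes that passed against 1 parent while the parents did not differ were kept apart, 1155 in the samples labelled triploid, 2240 in the doubled and 2285 in the stable hexaploid. In samples labelled triploid 16764 probes were like the maternal parent, 0 like the paternal parent, 1 between the parents and 1159 unresolved, with 3 above and 2 below both parents. The 3 were wheat0130Contig7209, wheat0130Contig1954 and MUGEST2003_23lib_Contig6252_p_1052, the 2 were wheat0130Contig6054 and wheat0130Contig4998, and the 1 between was wheat0130Contig4242. In the doubled hexaploid 6999 were like the maternal parent, 2777 like the paternal parent and 5830 between them. Another 1108 lay above and 2674 below both parents, 3782 together, which became 477 with normexp, 1999 with a 2-fold minimum and 7064 with array quality weights. In the stable hexaploid the corresponding counts were 8915, 1295, 5573, 164 and 441. The 605 probes outside the range of both parents in the stable hexaploid became 1916 with quantile normalization, 1164 with slide as a fixed block on 12 arrays, 1154 with median centring, 932 with the replicate block, 915 with array quality weights, 340 with only the groups compared in the fit, 305 with a 2-fold minimum and 29 with normexp. They became 293 without stable replicate 2, 225 and 359 without maternal replicates 1 and 2, and 1483 without stable replicate 3. Of those outside both parents 6.7 percent lay above with quantile normalization and 65.5 percent with normexp, so the direction of this split turned with normexp.

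**Figure D1:**
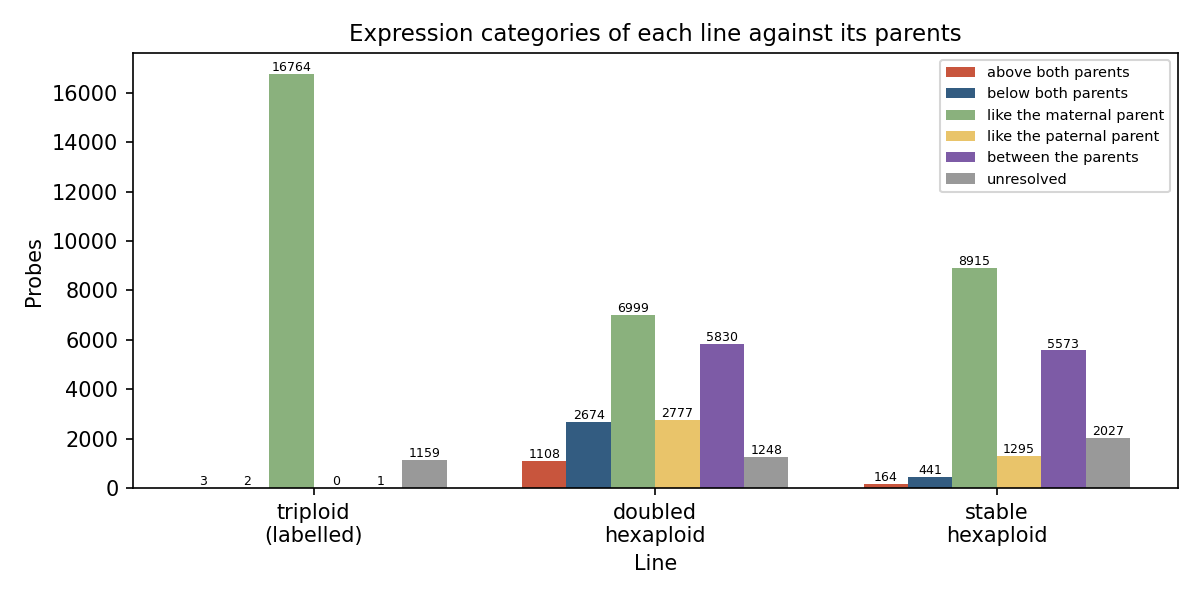
Bars give the number of probes (vertical axis) in each of 6 categories for each line (horizontal axis), with the number above each bar. In the samples labelled triploid, 16764 probes were like the maternal parent and 0 like the paternal parent, while 5830 in the doubled and 5573 in the stable hexaploid lay between the parents.

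The position of each line between the parents measured here was taken at probes at least 4-fold apart, where 0 is the paternal and 1 the maternal level on the log2 scale. At the 5570 maternal-higher probes it was 1 ± 0.005 (SD, n = 3) in the samples labelled triploid, 0.86 ± 0.006 in the doubled and 0.875 ± 0.012 in the stable hexaploid, beside 0.883 for the mid-parent. At the 3827 paternal-higher probes it was 0.963 ± 0.021, 0.444 ± 0.007 and 0.44 ± 0.008, beside 0.373 for the mid-parent. With quantile normalization the samples labelled triploid were at 1 there, so 0.963 is not read as a paternal contribution. The mid-parent was not rescaled, and bringing it down to the scale of the arrays would lower 0.883 and raise 0.373. Every sample labelled triploid lay above every hexaploid sample in both sets (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows; adjusted p = 0.15 over 6 tests). The hexaploids differed from each other by 0.004 at paternal-higher probes (exact p = 0.6) and by -0.015 at maternal-higher probes (exact p = 0.2, doubled minus stable). On the linear scale, the paternal share (0 at the maternal and 1 at the paternal level) was 0.003 ± 0.001, 0.21 ± 0.007 and 0.234 ± 0.007 in the 3 lines at paternal-higher probes, and 0 ± 0.023, 0.441 ± 0.011 and 0.394 ± 0.025 at maternal-higher probes.

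**Figure D2:**
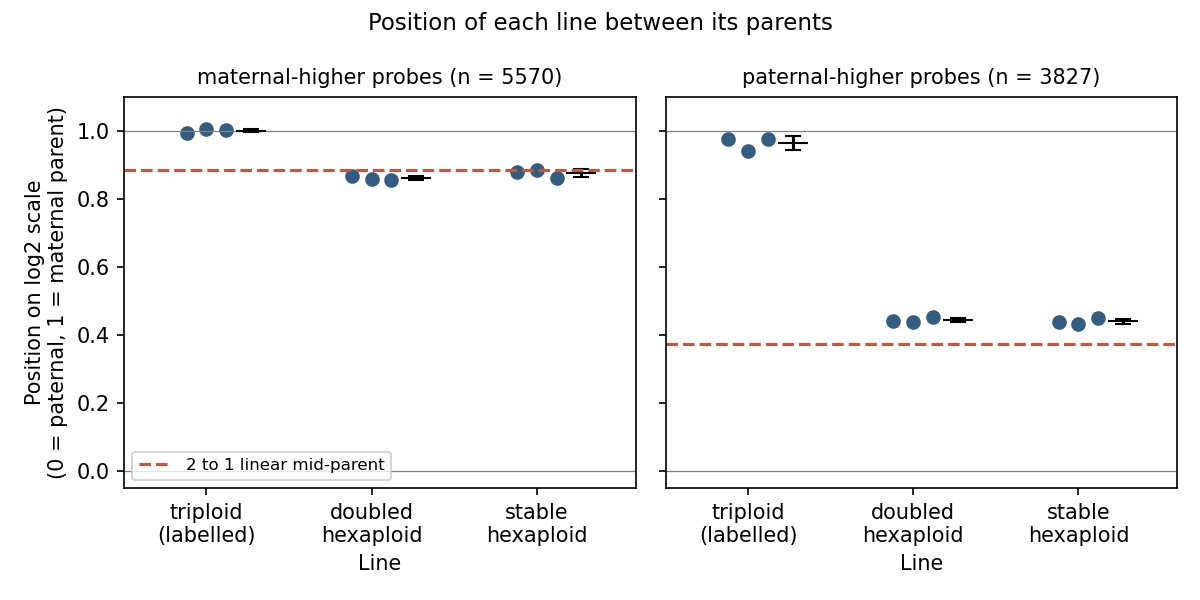
Points give the median position of each array between the parents on the log2 scale (vertical axis, 0 paternal and 1 maternal) for each line (horizontal axis), at 5570 maternal-higher probes and 3827 paternal-higher probes. The bar beside them is the mean with its SD and the dashed line the mid-parent, not rescaled. Samples labelled triploid sit at 0.963 and the hexaploids at 0.444 and 0.44 for paternal-higher probes.

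The doubled hexaploid was compared with the samples labelled triploid, the comparison the design gives for chromosome doubling. Since those samples differed from the maternal parent at 6 probes, it is close to the comparison with the maternal parent, which gave 13323 probes, and its calls cannot be read as effects of doubling. The doubled hexaploid and these samples differed at 13348 probes, 5771 higher and 7577 lower in the hexaploid. Of the higher ones 73.7 percent were paternal-higher, against 31.3 percent of all tested probes, and of the lower ones 58 percent were maternal-higher, against 32.1 percent of all. The widest rises were at rwhsh15n12 (11.64, SE 0.44) and whsh_allContig1255 (10.84, SE 0.39). Falls were widest at MUGEST2003_23lib_Contig8077_71 (-4.75, SE 0.44) and wheat0130Contig10488 (-4.55, SE 0.7). With normexp 3180 probes passed, 63.9 percent of them higher, in place of 43.2 percent. Slide and line cannot be told apart here either, since slide 4 held the doubled hexaploid alone.

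The stable hexaploid differed from the samples labelled triploid at 7853 probes, 3789 higher and 4064 lower, with 93.8 percent of the higher ones paternal-higher and 75.5 percent of the lower ones maternal-higher. Here too rwhsh15n12 (11.52, SE 0.44) and whsh_allContig1255 (11.08, SE 0.39) rose most, and wheat0130Contig1954 (-3.61, SE 0.41) and MUGEST2003_23lib_Contig9302_636 (-3.48, SE 0.27) fell most. Both falls missed the threshold with normexp, where 2092 probes passed and 89.1 percent of them were higher, in place of 48.2 percent. The balance of higher and lower calls, near even, turned in 6 of 15 other settings and without any 1 array of the triploid or maternal group, doubled replicate 2 or 3 or stable replicate 2, with 61 percent higher at most among these arrays. Within slides 1, 2 and 3, 5767, 8841 and 6848 probes differed at least 2-fold.

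The hexaploids differed from each other at 11422 probes, 5794 higher and 5628 lower in the stable one. The widest rises were at whsh_allContig984 (5.38, SE 0.31), at 4.34 in the stable and -1.04 in the doubled hexaploid, and wheat0130Contig5472 (4.93, SE 0.53). MUG020A12R990620 fell by 4.75 (SE 0.46) and wheat0130Contig8620 by 4.6 (SE 0.7), and both missed the threshold with normexp. The count was 1109 with normexp and 6825 with only these groups in the fit, and the near-even balance turned in 5 of 14 other settings, down to 45.1 percent higher from the deposited table, and without stable replicate 1 (48.4 percent higher) or 3 (48.6). Slide and line cannot be told apart. Their departures from the mid-parent overlapped at 88 higher and 490 lower probes, where independent lists would share 23 and 425. Another 224 probes were called in opposite directions, a number for which no count from independent lists was computed, so it is not read as an excess. The covariance of the departures across probes was -0.0155 (r = -0.03), below the 0.0426 (r = 0.41) that the shared parents alone gave in simulation. With 3 arrays per parent the parents could not be divided, so the overlap includes whatever the shared parents contribute.

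The 6 probes named for genes were RD29A, RD29B, cor47, Wcor15, DREB2A and DREB2B, all names known from cold or drought responses of plants. Whether these probes match transcripts of the lines measured here was not tested. A missing signal therefore does not show that a gene is off, and a call may not be for the gene named. RD29A was well above background on 1 of 15 arrays, and cor47, DREB2A and DREB2B on none. Wcor15, a cold-responsive gene of wheat, was well above background on 1 of 3 maternal arrays and on 3 of 3 arrays of the paternal parent, the samples labelled triploid and the doubled hexaploid, and on 2 of 3 stable hexaploid arrays. Calls above the mid-parent passed in the samples labelled triploid (adjusted p = 0.01653, limma) and the doubled hexaploid (adjusted p = 0.0143, limma). Against the maternal parent the doubled hexaploid passed, higher (adjusted p = 0.005397, limma), and the samples labelled triploid did not (adjusted p = 0.4268, limma). With the maternal level at the floor no size is given for these. Against the paternal parent the log2 difference was 0.56 (SE 0.31, adjusted p = 0.1373, limma) in the samples labelled triploid and 0.52 (SE 0.31, adjusted p = 0.164) in the doubled hexaploid, and neither passed. Wcor15 was lower in the stable hexaploid, with 1 array near the floor, than in the doubled one (-0.95, SE 0.31, adjusted p = 0.02806) and the samples labelled triploid (-0.99, SE 0.31, adjusted p = 0.03186), and both passed. RD29B was well above background on 3 of 3 maternal, 3 of 3 stable hexaploid, 2 of 3 paternal and 1 of 3 arrays labelled triploid, and on 0 of 3 doubled hexaploid arrays. Its level in the doubled hexaploid was called lower than in the maternal parent (adjusted p = 0.009469, limma), the mid-parent (0.02145) and the stable hexaploid (0.02167). The maternal parent was called higher than the paternal parent (adjusted p = 0.04948, limma). With low levels near the floor no size is given.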

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

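Tests of the held-out maternal arrays, the additive share, silencing, the slide of the doubled hexaploid as a random block, the GC and brightness trend and the rescaled mid-parent were chosen only after the result was seen. No group had 4 samples, so no array was tested as an outlier.

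Samples labelled triploid matched the maternal parent. An additive hybrid is argued against by their paternal share of 0.003 at paternal-higher probes, where the hexaploids had 0.21 and 0.234, and scaling by a highest share of 0.0345 on any of these arrays under quantile, median or normexp settings. RNA without a paternal-genome contribution, as from maternal-type plants or a mislabelled sample, is a candidate explanation. Paternal-only probes were chosen without maternal replicate 1, 2 or 3 in turn, giving 1576, 1402 and 1586 probes. On average 8.6, 5.4 and 8.8 percent of them were seen on the arrays labelled triploid, and 11.9, 1 and 12.5 percent on the left-out maternal array. The mean difference was -0.9 percentage points, but the 3 differences had both signs and partly cancelled. On slides 1, 2 and 3, 177, 28 and 208 of these probes were seen on the array labelled triploid and 188, 14 and 198 on the left-out maternal array. Every array of the doubled hexaploid showed at least 929, 834 and 929 of them. A paternal genome present but silent stays open, since RNA alone cannot separate a silent from an absent genome. Of 8839 paternal-higher probes, 2 were above the maternal parent, wheat0130Contig7209 and wheat0130Contig4242. The former lay above the paternal parent too, and the latter was near the floor, so neither decides on silencing.

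The doubled and stable hexaploids differed at 11422 probes. A trend with GC content or brightness is argued against as the whole cause, since 81.2 percent of these probes stayed called in the same direction after its removal, while the correlation of the difference with GC content went from 0.27 to 0. The slide cannot be told apart from the line, because slide 4 held the doubled hexaploid alone; with slide as a random block 10194 probes were called. A difference between a newly doubled and a stable line, or between parental stocks, on which the labels are silent, remains open and untested.

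Calls against the mid-parent were mostly lower in the hexaploids, 74.9 percent in the doubled and 85.8 percent in the stable one. The scale of the mid-parent contributes by construction, since its 75th percentile lies 0.201 above that of the arrays. With the mid-parent rescaled, the median departure went from -0.23 to -0.03 in the doubled and from -0.24 to -0.04 in the stable hexaploid. Then 56 and 52.9 percent of calls were lower. Taking 1 constant from every probe evens the balance by construction, so these percentages do not show whether the scale is the whole cause. A GC or brightness trend is argued against as the whole cause, since after its removal 77.6 percent of the stable hexaploid's calls were lower, though the calls themselves went from 1792 to 1091, of which 1011 were among the first. Lower expression of the hexaploids as such was not tested, since array scaling removes it.

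Other divisions of the same arrays were counted. For 3 against 3 there are 10, too few for a share under 0.05. In each of these comparisons 1 division, the real one, gave as many calls. The highest of the others was 0 for maternal versus paternal parent (real 17928), 4 for triploid versus maternal parent (6), 0 for triploid versus paternal parent (17925), 0 for doubled hexaploid versus maternal parent (13323) and 0 versus paternal parent (17917). It was 1 for stable hexaploid versus maternal parent (7831), 0 versus paternal parent (17020), 1 for doubled hexaploid versus triploid (13348), 16 for stable versus doubled hexaploid (11422) and 0 for stable hexaploid versus triploid (7853). Where the groups shared slides, 4 divisions parted every slide, and the highest of the others was 0. Against the mid-parent, 4 of 100 drawn divisions gave as many calls in the triploid (real 5853, highest other 18895). In the doubled hexaploid 4 did (10434, 15753), and both shares are under 0.05. In the stable hexaploid 7 of 100 did (1792, 17495). Of these divisions, the real one included, 4, 4 and 5 kept the paternal arrays together. The share thus mostly counts how often the draw kept those arrays together, and the draw did not respect slides. For none of the 3 lines does it decide whether the departures arose by chance.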

How the results depend on the processing

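Slide as a random block, the rescaled mid-parent, the trend removal and 1 probe per sequence cluster were chosen after seeing the data. In this part the lines are called triploid (the samples labelled so), doubled and stable, and the parents maternal and paternal. Of 331 combinations of a result and another setting, leaving out arrays apart, 221 kept the count within 1.5 times or the position within 1 SD, and 110 did not. The 30 named probe values had 911 combinations, leaving out arrays included, with 0 changes of sign: 867 kept the call and 44 lost it. wheat0130Contig11839 versus mid-parent lost it in 13, as did wheat0130Contig1954 in triploid versus maternal. Signal over background limits dim probes, and 63.7 to 75.3 percent of probes were well above background per array. Normexp, with an offset of 50, shrinks differences of dim probes by construction. Fewer probes were tested when all 15 arrays had to be well above background (19111) and from the deposited table (20726). The cause of the other shifts was not tested. Choosing 1 probe per gene was not possible without gene names, and gene list settings were not run. With 1 probe per sequence cluster each count stayed within 1.5 times. The replicate number marks the slide for 4 groups, and of the counts the replicate block moved only the 2 given below by over 1.5 times. Over these settings and the fits without 1 array, where any probe was called, the share of higher calls, in percent, ran from 41.5 to 53.6 for maternal versus paternal (50.7), 0 to 100 for triploid versus maternal (66.7), 41.9 to 54.7 for triploid versus paternal (51.6), 39.9 to 64.1 for doubled versus maternal (45.4), 35.7 to 50.9 for doubled versus paternal (46.7), 41.2 to 89.4 for stable versus maternal (51.6), 31 to 51 for stable versus paternal (44.5), 39.1 to 63.9 for doubled versus triploid (43.2), 45.1 to 55.6 for stable versus doubled (50.7), 43.3 to 89.1 for stable versus triploid (48.2), 0.5 to 60.3 for triploid versus mid-parent (18.2), 14.6 to 58.1 for doubled versus mid-parent (25.1) and 5.1 to 72 for stable versus mid-parent (14.2). In the last 3 the top came with a 2 to 1 mean of log2 values. The balance turned for stable versus triploid in 6 of 15 settings and 9 of 15 fits without 1 array. Of probes outside both parents in stable, 6.7 to 65.5 percent lay above, and in doubled 15.4 to 37.4. The median log2 difference of all probes for maternal versus paternal went from -0.05 to -0.31 with median centring and -0.44 with normexp.

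With quantile normalization, the count was 7165 for stable versus mid-parent, and those outside both parents were 1916 in stable. The maternal-higher position was 0.994 in triploid, 0.828 in doubled and 0.858 in stable, and the paternal-higher 1 in triploid, 0.522 in doubled and 0.509 in stable. With median centring, the count was 6610 for stable versus mid-parent, and those outside both parents were 1154 in stable. The maternal-higher position was 0.841 in doubled, and the paternal-higher 0.529 in doubled and 0.513 in stable. With normexp background correction, counts were 9421 for maternal versus paternal, 0 for triploid versus maternal, 9297 for triploid versus paternal, 3380 for doubled versus maternal and 7203 for doubled versus paternal. There were also 2193 for stable versus maternal, 6111 for stable versus paternal, 3180 for doubled versus triploid, 1109 for stable versus doubled and 2092 for stable versus triploid. There were also 2131 for triploid versus mid-parent, 1342 for doubled versus mid-parent and 4 for stable versus mid-parent, and those outside both parents were 0 in triploid, 477 in doubled and 29 in stable. The maternal-higher position was 0.784 in doubled and 0.822 in stable, and the paternal-higher 0.471 in doubled and 0.412 in stable. From the deposited value table, counts were 11755 for maternal versus paternal, 1 for triploid versus maternal, 11816 for triploid versus paternal, 11705 for doubled versus paternal and 4584 for stable versus maternal. The count was 4735 for stable versus triploid, and those outside both parents were 1 in triploid. Without the filter on dim probes, counts were 3 for triploid versus maternal and 1009 for stable versus mid-parent, and those outside both parents were 3 in triploid. The paternal-higher position was 0.451 in doubled. With probes well above background on all 15 arrays, counts were 11012 for maternal versus paternal, 1 for triploid versus maternal, 11077 for triploid versus paternal, 8315 for doubled versus maternal and 10870 for doubled versus paternal. There were also 4378 for stable versus maternal, 10618 for stable versus paternal, 8307 for doubled versus triploid, 4500 for stable versus triploid and 3565 for triploid versus mid-parent, and those outside both parents were 1 in triploid. The maternal-higher position was 0.788 in doubled and 0.829 in stable, and the paternal-higher 0.527 in doubled and 0.506 in stable. With the replicate block, the count was 2889 for stable versus mid-parent, and those outside both parents were 932 in stable. With slide as a fixed block on the 12 arrays of the other groups, counts were 1 for triploid versus maternal and 4047 for stable versus mid-parent, and those outside both parents were 1 in triploid and 1164 in stable. With slide as a random block, counts were 14 for triploid versus maternal and 3238 for stable versus mid-parent, and those outside both parents were 8 in triploid. With array quality weights, counts were 139 for triploid versus maternal, 11964 for triploid versus mid-parent, 17501 for doubled versus mid-parent and 2885 for stable versus mid-parent, and those outside both parents were 54 in triploid, 7064 in doubled and 915 in stable. With a 2-fold minimum, counts were 8778 for doubled versus maternal, 4815 for stable versus maternal, 8827 for doubled versus triploid, 7290 for stable versus doubled and 4853 for stable versus triploid. There were also 3673 for triploid versus mid-parent, 5311 for doubled versus mid-parent and 1028 for stable versus mid-parent, and those outside both parents were 1999 in doubled and 305 in stable. With only the groups compared in the fit, counts were 0 for triploid versus maternal, 6825 for stable versus doubled and 603 for stable versus mid-parent, and those outside both parents were 0 in triploid and 340 in stable. Against a 1 to 1 linear mid-parent, counts were 11205 for triploid versus mid-parent and 6033 for stable versus mid-parent. Against a 2 to 1 mean of log2 values, counts were 9211 for triploid versus mid-parent and 7310 for stable versus mid-parent. Against a 1 to 1 mean of log2 values, counts were 13083 for triploid versus mid-parent and 9866 for stable versus mid-parent. Against a mid-parent rescaled to its own 75th percentile, the count was 607 for stable versus mid-parent. After removal of the GC and brightness trend, the count was 1091 for stable versus mid-parent. The maternal-higher position was 0.994 in triploid, 0.844 in doubled and 0.892 in stable, and the paternal-higher 0.414 in stable. With probes at least 2-fold apart between the parents, the maternal-higher position was 0.832 in doubled and 0.846 in stable, and the paternal-higher 0.518 in doubled and 0.545 in stable. With probes at least 8-fold apart between the parents, the maternal-higher position was 0.877 in doubled and 0.89 in stable, and the paternal-higher 0.376 in doubled and 0.363 in stable.

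Over the 15 fits without 1 array each, counts ran from 16568 to 18625 for maternal versus paternal, 1 to 11 for triploid versus maternal, 16517 to 18620 for triploid versus paternal and 10887 to 14393 for doubled versus maternal. They ran from 16292 to 18754 for doubled versus paternal, 5120 to 8754 for stable versus maternal, 15170 to 17591 for stable versus paternal and 10952 to 14402 for doubled versus triploid. For the others, ranges were 8466 to 11695 for stable versus doubled, 5274 to 8874 for stable versus triploid, 4492 to 6600 for triploid versus mid-parent and 7654 to 11557 for doubled versus mid-parent. Last, the range was 499 to 3413 for stable versus mid-parent. Probes outside the range of both parents ran from 1 to 8 in triploid, 2868 to 4466 in doubled and 225 to 1483 in stable. The maternal-higher position ran from 0.997 to 1.003 in triploid, 0.857 to 0.863 in doubled and 0.871 to 0.882 in stable. The paternal-higher position ran from 0.952 to 0.975 in triploid, 0.44 to 0.448 in doubled and 0.431 to 0.45 in stable. Leaving out 1 array moved counts by over 1.5 times as follows. Stable versus mid-parent was 737 without paternal replicate 1, 1020 without paternal replicate 2, 1069 without triploid replicate 1, 1182 without triploid replicate 3, 647 without maternal replicate 1, 986 without maternal replicate 2, 1174 without maternal replicate 3, 2832 without doubled replicate 1, 499 without stable replicate 2 and 3413 without stable replicate 3. Triploid versus maternal was 2 without paternal replicate 1, 3 without paternal replicate 2, 11 without triploid replicate 1, 2 without maternal replicate 1, 1 without maternal replicate 3, 3 without doubled replicate 3 and 10 without stable replicate 2. Stable versus maternal was 5120 without maternal replicate 1. Probes outside both parents in stable numbered 225 without maternal replicate 1, 359 without maternal replicate 2, 293 without stable replicate 2 and 1483 without stable replicate 3, and in triploid 2 without paternal replicate 1, 3 without paternal replicate 2, 8 without triploid replicate 1, 2 without triploid replicate 2, 2 without maternal replicate 1, 3 without maternal replicate 2, 1 without maternal replicate 3 and 3 without doubled replicate 3. The 2 arrays left in such a group are assumed to vary like the other groups.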

Other observations

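The test on near-identical probes was chosen after the result was seen. Probes of near-identical sequence were compared for the log2 ratio of maternal to paternal parent. In 194 pairs of probes with identical sequence the ratios differed by a median of 0.0457, and in 25 pairs that differ at 1 base by 0.1. In 35 pairs that differ at 2 to 9 of the 60 bases the median was 0.82, with quartiles of 0.102 and 2.18. Of these 35 pairs 17 differed over 2-fold and 6 were called at least 2-fold in opposite directions, against 0 of the identical pairs. The difference of medians was 0.774 (one-sided permutation test, 100000 resamples, p = 1e-05, the smallest they can give). Some pairs share a probe, so they are not independent as the test assumes, and its p is likely too small. A hypothesis is that the match of a probe to the transcript of 1 parent contributes to some parental differences on this array; related genes regulated apart could give the same, and the sequences of the parents were not used here.

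New signals in the lines were few. Of 6611 probes seen on none of the 6 parental arrays, 9 were seen on all 3 arrays labelled triploid, 11 in the doubled and 17 in the stable hexaploid. Stable replicate 2 stood apart: within slide 2, 7003 probes lay at least 2-fold from the mid-parent, against 2763 and 2720 on slides 1 and 3.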
